A study of Mus musculus with 5 samples.

How the data were processed

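The study measured polyadenylated RNA in 5 libraries of CD31-positive cells from mouse hearts 5 days after myocardial infarction, 3 control and 2 Tbx1cko. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was isolated with TRIzol LS and libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and the tools included STAR 2.5.2b, DESeq, R 3.5.1 and DESeq2 1.20.0. The read counter, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical gene copies, may be split in ways that cannot be seen in the counts.

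The deposited values are a signal per gene, a read count divided by a size factor of its library, for 17638 genes named by symbol. Every value was a whole multiple of the smallest value above 0 of its library, within 0.01, so 100% of values gave whole reads. Median-of-ratios size factors recomputed from those reads matched the divisors to a relative difference of 3.9e-15. The reads of a gene summed over the libraries were at least 12. No row lacked a gene name. Recovered reads per library came to 14689782, 18617284 and 17338772 for control replicates 1 to 3 and 17769729 and 16061666 for Tbx1cko replicates 1 and 2. The most abundant gene took 0.819% to 1.09% of a library's reads and the top 10 took 5.18% to 6.24%. A gene near the filter of 10 reads rests on few reads.

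Genes with a mean normalised count of at least 10 over the 5 libraries were tested, 14339 in all. limma 3.58.1 (R 4.3.3) was fitted to log2(normalised count + 1) with genotype as the only term and a trended prior, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2 scale with a pseudocount of 1, which understates the change of low genes. Adjusted p-values are from limma unless another tool is named. Means are given with the SD over libraries. Gene lists, 40 in all, were fixed before the data were examined, as were the tests, the groups and the rule for naming genes. The 37 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over the 37. A list of epicardial genes had 3 of 11 members tested, a list of mitochondrially encoded genes 0 of 15, and Tbx1 formed a list of 1. These 3 were not tested as lists. Camera compares a list with the other genes, and fry asks whether its genes move, on balance, in a single direction, or, in its mixed form, in either direction. Counts adjusted over the list alone apply the adjustment to the members only.

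The rule for naming genes took Tbx1 first, then up to 12 genes per direction past the threshold, with the largest log2 differences, whose groups did not overlap and whose higher group mean was at least 50, filled up to 6 by the smallest unadjusted p under the same conditions where fewer passed. Predicted genes without a name were left out. From each list described, up to 4 members with the smallest unadjusted p were named. Prox1, Reln, Mmrn1, Lyve1, Lyz2, Rgs5, Des, Ddx3y, Cyp26b1, Myl7, Sln, Adamts4, Steap4, Tlr13 and Bcl2l1 fall outside this rule and were chosen after their values were seen.

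Because whole reads were recovered, edgeR 4.0.16, DESeq2 1.42.0 and voom were run on them as alternatives. Other alternatives fixed beforehand were pseudocounts of 0.5 and 5, no filter, a filter at 50, TMM scaling, quantile normalisation, no trend, a robust prior, a replicate block, thresholds of 0.1 and of a log2 difference of 1, and leaving out each library. Alternatives added after the data were seen were a correction for GC content (a loess of each library's deviation on GC percent, span 0.3), limma's sample weights, edgeR, DESeq2 and the GC correction without control replicate 2, and the lymphatic endothelial list without Tbx1. GC content and gene positions came from GENCODE M21 on GRCm38, by symbol, with 16771 symbols matched. Of the genes tested, 13771 (96%) had a GC value. Fam65c had no match, so no position was given for it.

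Replicates were compared before they were averaged. The chi-square per degree of freedom between recovered reads of a pair was 14.33 for control replicates 1 and 3 and 17.1 for the Tbx1cko pair, above sampling noise, so no library was treated as a duplicate. The tests were checked on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold among 14339. With the dispersion of all 5 libraries, limma and edgeR called 0% of both sizes, and DESeq2 called 11% of the 2-fold and 74% of the 4-fold changes but also 66 unchanged genes. With the dispersion of the 4 libraries without control replicate 2, limma called 67% and 94%, edgeR 67% and 95%, and DESeq2 69.5% and 93.8%, with 9, 15 and 6 unchanged genes called. In both simulations camera called a list that had been shifted and 0 of the other 36. Genes were drawn independently there, with no GC trend of a library, so members of a list could not move together. The simulations thus do not show how often camera at the preset correlation calls lists in error in the real libraries.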

Results

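Polyadenylated RNA was sequenced from CD31-positive cells of mouse hearts 5 days after myocardial infarction. CD31, or Pecam1, is a surface protein of endothelial cells that platelets and some leukocytes also carry. There were 3 libraries from controls and 2 from a conditional knockout called Tbx1cko, which the series describes as endothelial. The mice were 2 months old, with a C57BL/6 background. The deposited table held a normalised read count for 17638 genes. The reads behind those counts came to 14689782, 18617284 and 17338772 in control replicates 1 to 3 and 17769729 and 16061666 in Tbx1cko replicates 1 and 2. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries. Reads of Xist and of Y-linked genes, given below, show that the 2 Tbx1cko libraries came from different animals. Among the controls the spread may be technical.

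The comparison asked how the transcriptome of these CD31-positive cells, which need not all be endothelial, differed after infarction when Tbx1 was deleted. Tbx1 encodes a T-box transcription factor needed in the embryo for the pharyngeal arches and for lymphatic vessel growth. The gene (ENSMUSG00000009097.10) lies on the minus strand of chromosome 16, from 18580979 to 18590671 in GRCm38, and is protein-coding. Its normalised read counts were 64.4, 72.7 and 69.6 in control replicates 1 to 3 and 18.3 and 17.3 in Tbx1cko replicates 1 and 2. The means were 68.9 ± 4.18 (SD, n = 3) and 17.8 ± 0.684 (SD, n = 2), with no overlap between the groups. The fitted log2 difference, on log2(normalised count + 1), was -1.89 (SE 0.297), or 3.71-fold lower, with a limma adjusted p of 0.762 over all genes tested and a DESeq2 adjusted p of 0.0349. Over all alternative settings its lowest adjusted p was 0.0127, with limma's sample weights, whose estimation stopped before it converged. The values go with the genotypes on the labels, and the labels do not say which part of the gene was deleted.

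With limma, 0 of 14339 genes passed an adjusted p of 0.05. The count at an unadjusted p under 0.05 was 250 genes, 53 higher and 197 lower in Tbx1cko, where chance gives about 717. The excess of lower genes was smaller without control replicate 2, at 486 higher and 584 lower. By the other tools run on the recovered reads, edgeR called 0 genes, voom called 0, and DESeq2 called 4, which were Myt1l higher and Tbx1, Selp and Myl7 lower. The groups did not overlap for 2030 genes higher and 1991 genes lower in Tbx1cko, 28% of those tested, where chance gives 20%.

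Control replicate 2 stood apart from the other libraries. Its log2 values correlated across genes with those of the others at r between 0.859 and 0.889, while the other 4 libraries correlated with each other at 0.98 to 0.988. Genes are not independent replicates, so these coefficients describe the libraries. Its deviation from the other libraries followed the GC content of the transcripts, with a Spearman rho of 0.801 across genes. The log2 differences between Tbx1cko and control followed GC content too, with a rho across genes of -0.713 over all 5 libraries and still -0.305 without control replicate 2, so leaving out this library did not remove the trend. Without it, limma called 3 genes, Selp and Cyp26b1 lower and Myt1l higher, each at an adjusted p of 0.0203, and 1070 genes had an unadjusted p under 0.05. In fits added after the data were seen, again without this library, edgeR called 1 gene, DESeq2 called 65 (26 higher, 39 lower), and limma after GC correction called 0.

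**Figure D1:**
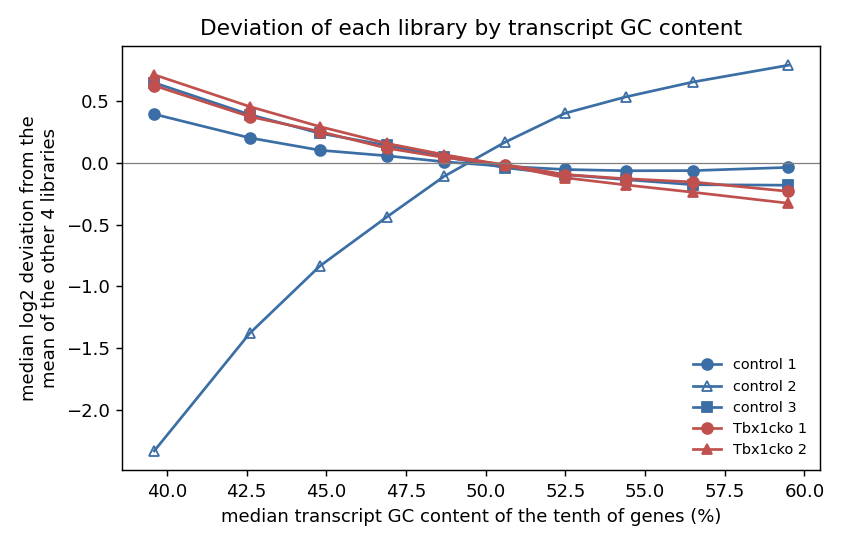
Median log2 deviation of each library from the mean of the other 4 libraries (vertical axis) in 10 equal sets of the tested genes ordered by transcript GC content (horizontal axis, percent). Control replicate 2 (open triangles) runs from -2.33 in the genes poorest in GC to 0.79 in those richest in GC, while the other 4 libraries run from 0.39 to 0.71 down to between -0.33 and -0.04. The mean that each of these 4 is compared with includes control replicate 2, so part of their opposite slope comes from that library.

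The naming rule gave the genes with non-overlapping groups and the smallest unadjusted p, 6 in each direction. All missed the limma threshold, at an adjusted p of 0.762 each. Selp, the endothelial adhesion receptor P-selectin, had 3542 ± 206 normalised reads in controls (SD, n = 3) and 1577 ± 301 in Tbx1cko (SD, n = 2), a log2 difference of -1.18 (SE 0.202). Lrrc32, which encodes GARP, a surface receptor that holds latent TGF-beta, had 5366 ± 1251 and 2619 ± 10.5, a log2 difference of -1.01 (SE 0.242) that GC correction moved to -0.67. The nerve growth factor receptor gene Ngfr had 89.8 ± 14.9 in controls and 30.2 ± 3.83 in Tbx1cko. Susd2 had 371 ± 29.7 and 193 ± 10.5, and Fam65c 64.6 ± 7.82 and 25.6 ± 2.64. With Tbx1, these are the 6 genes lower in Tbx1cko.

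On the higher side, Fkbp5, a co-chaperone of the glucocorticoid receptor, had 1199 ± 327 normalised reads in controls and 2510 ± 600 in Tbx1cko, a log2 difference of 1.08 (SE 0.307). Pf4, platelet factor 4, had 1521 ± 430 and 2825 ± 139, and the myeloid receptor gene Cd300lf 242 ± 29.8 and 478 ± 98.5. The leukocyte receptor gene Sirpb1c had 54.9 ± 43.8 in controls and 199 ± 10.7 in Tbx1cko, a log2 difference of 2.11 that GC correction moved to 1.19, and it has close paralogs, so its count is uncertain. Siglecf had 16.9, 24.8 and 24.5 in control replicates 1 to 3 and 60.4 and 44.8 in Tbx1cko. Myt1l, a neuronal transcription factor gene, had 1.1, 1.8 and 0 normalised reads in the controls and 43.9 and 125.3 in Tbx1cko. Its log2 difference of 5.37 (SE 0.753) depends on the pseudocount, because the controls held almost no reads.

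Of 37 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 17, 5 higher and 12 lower in Tbx1cko. With an estimated correlation it called 0, with a smallest adjusted p of 0.557, and fry, tested for a single direction, called 0, with a smallest adjusted p of 0.381 and 3 lists at an unadjusted p under 0.05. Tested for change in either direction, fry called 1 list, the lymphatic endothelial list (adjusted p = 0.0057), and 0 once Tbx1 was left out of that list (adjusted p = 0.0769). Each direction below is thus a call with the preset correlation only. No member of any list passed the limma threshold over all genes. Without control replicate 2, camera called 22 lists, and 15 of the 17 kept their call and direction. With an estimated correlation 0 of these 22 were called, with a smallest adjusted p of 0.349. After GC correction with all 5 libraries, the medians moved by more than 1.5 times for the immediate early list (-0.70 to -0.42), Notch signalling (-0.43 to -0.23), TGF-beta signalling (-0.38 to -0.25), fatty acid genes (0.28 to 0.11), angiogenic sprouting (-0.13 to -0.01) and ribosomal proteins (-0.19 to -0.08). Several lists share genes, such as Notch3 in the mural and Notch lists and Foxc2 in both lymphatic lists.

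The lymphatic endothelial list was lower in Tbx1cko, with 15 of 19 members lower, a median log2 difference of -0.35 and a camera adjusted p of 5.701e-05 (adjusted p = 0.557 with an estimated correlation). Tbx1, which the genotype lowers, is a member of this list. Without it, a test added after the data were seen, 14 of 18 members were lower, with a median of -0.24 and a camera adjusted p of 0.000515 (adjusted p = 0.557 with an estimated correlation). Adjusted over the list alone, 1 member passed, Tbx1 itself. Foxc2, a transcription factor of lymphatic valves, had 322 ± 83.5 normalised reads in controls (SD, n = 3) and 140 ± 11.8 in Tbx1cko (SD, n = 2), a log2 difference of -1.17 (SE 0.299) that GC correction moved to -0.71. Ccl21a, the chemokine that draws dendritic cells into lymphatic vessels, had 3305 ± 572 and 1716 ± 392, and Thy1 had 1058 ± 122 and 547 ± 115. Ccl21a has near-identical copies in the mouse genome, so its count is uncertain. Lyve1, a lymphatic and macrophage receptor, had 1130 ± 336 and 1079 ± 170. The list's median depended on single control libraries. It was -0.51 without control replicate 2, -0.22 without control replicate 1, and -0.04 without control replicate 3, where the call was lost at an adjusted p of 0.0533.

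Without control replicate 2, 11 members of the lymphatic endothelial list passed adjusted over the list alone, all lower, or 10 of 18 with Tbx1 left out. In the DESeq2 fit without that library, which was added after the data were seen, 7 of the 19 members passed over all genes, all lower, which is Tbx1 and 6 of the other 18. They included Prox1, the master transcription factor of lymphatic identity, at a log2 difference of -0.83 (adjusted p = 0.0456), Reln at -0.71 (adjusted p = 0.0404) and Mmrn1 at -0.95 (adjusted p = 0.00393). These 3 genes were chosen after their values were seen. Prox1 had 335.6, 147.2 and 430.9 normalised reads in control replicates 1 to 3 and 225.9 and 207.9 in Tbx1cko. The low value of control replicate 2 lay below both Tbx1cko values. The lymphangiogenic signalling list was also lower, with 14 of 16 members lower, a median of -0.22 and a camera adjusted p of 0.00661 (adjusted p = 0.557 with an estimated correlation). Its receptor gene Flt4, which encodes VEGFR3, had 5861 ± 1630 in controls and 4022 ± 476 in Tbx1cko, a log2 difference of -0.51 that was -0.30 without control replicate 2.

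**Figure D2:**
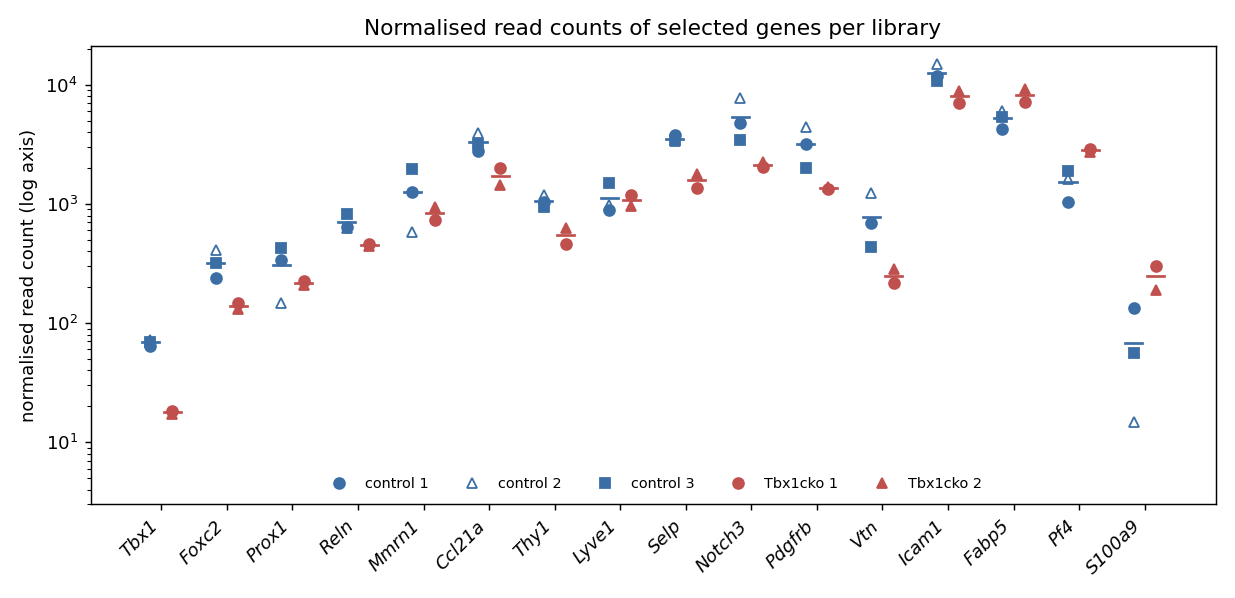
Normalised read counts (log axis) of 16 genes in each library, with controls in blue and Tbx1cko in red; horizontal bars are group means and the open triangle is control replicate 2. Tbx1 lies at 64.4 to 72.7 in controls and 17.3 to 18.3 in Tbx1cko, and all genes but Tbx1 were picked for display after their values were seen.

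The mural cell list, markers of pericytes and smooth muscle cells, was lower in Tbx1cko. Of its 15 members 14 were lower, the median log2 difference was -0.81, and the camera adjusted p was 2.161e-10 (adjusted p = 0.557 with an estimated correlation). The groups did not overlap for 13 members, all lower, where chance gives 10% per direction. Over all genes tested, 1991 of 14339 were lower without overlap. Pdgfrb, the pericyte growth factor receptor, had 3195 ± 1202 normalised reads in controls (SD, n = 3) and 1371 ± 35.9 in Tbx1cko (SD, n = 2). Notch3 had 5343 ± 2221 and 2137 ± 138, a log2 difference of -1.24 (SE 0.366), and Vtn had 784 ± 408 and 250 ± 46.3, a difference of -1.53 (SE 0.471). The potassium channel subunit gene Abcc9 had 2263 ± 214 and 1490 ± 148. Adjusted over the list alone, 0 members passed with all libraries (limma, 8 at an unadjusted p under 0.05) and 14 passed without control replicate 2, where the median was -0.60. DESeq2 without that library called 6 of the 15 over all genes, all lower.

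Endocardial markers and genes of Notch and TGF-beta signalling were lower in Tbx1cko as well. The endocardial list had 10 of 10 members lower, with a median of -0.50 and a camera adjusted p of 5.542e-05. Its transcription factor gene Gata4 had 348 ± 150 normalised reads in controls and 175 ± 31.0 in Tbx1cko, and Nfatc1 had 1924 ± 246 and 1366 ± 228. In the Notch signalling list 14 of 16 members were lower, with a median of -0.43 and an adjusted p of 8.894e-05. Notch1 had 10516 ± 4177 and 5713 ± 1025, and the target gene Heyl 557 ± 163 and 271 ± 52.9. The list of TGF-beta, BMP and mesenchymal transition genes had 17 of 24 members lower, with a median of -0.38 and an adjusted p of 0.00319. With an estimated correlation the adjusted p of these 3 lists was 0.557 each. Without control replicate 2 the medians were -0.43 for the endocardial, -0.21 for the Notch and -0.22 for the TGF-beta list. Adjusted over the list alone, 0 endocardial, 3 Notch and 0 TGF-beta members then passed in limma, the Notch members all lower. DESeq2 without that library called 0, 1 and 0 members of these lists over all genes. The Notch member was Notch3, lower at a log2 difference of -0.96 (DESeq2 adjusted p = 9.78e-05). Notch3 is also a member of the mural cell list, so this call is not separate from the mural calls. Without control replicate 2 the log2 difference of Gata4 moved from -0.92 to -0.59 and that of Notch1 from -0.82 to -0.52. GC correction with no library left out moved the log2 difference of Nfatc1 from -0.50 to -0.30. The TGF-beta call was lost without Tbx1cko replicate 1, at a median of -0.25 and an adjusted p of 0.052, which leaves 1 Tbx1cko library assumed to vary like the controls.

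The venous list was lower, with 8 of 12 members lower, a median of -0.27 and a camera adjusted p of 0.00685 (adjusted p = 0.557 with an estimated correlation). Adjusted over the list alone, Selp passed, at 0.0185. Vwf, von Willebrand factor, had 15763 ± 5810 normalised reads in controls and 10145 ± 647 in Tbx1cko. The venous call was lost without control replicate 1, at an adjusted p of 0.0985, and without control replicate 3, at 0.106. The arterial list had 12 of 15 members lower, a median of -0.27 and an adjusted p of 0.00685 (adjusted p = 0.686 with an estimated correlation). Dll4, an arterial Notch ligand, had 6042 ± 1755 and 4210 ± 360. Without control replicate 2 the log2 difference of Vwf moved from -0.58 to -0.29 and that of Dll4 from -0.49 to -0.26. The arterial median was -0.16 without control replicate 2, and the call was lost without Tbx1cko replicate 1, at an adjusted p of 0.052, and with sample weights, at -0.14 and 0.0833. The pan-endothelial list had 14 of 18 members lower, with a median of -0.17 and an adjusted p of 0.0314 (adjusted p = 0.686 with an estimated correlation), which became -0.08 and 0.0808 without control replicate 2. Without Tbx1cko replicate 2 it was -0.17, with an adjusted p of 0.0865. Quantile normalisation also ended the pan-endothelial call, at -0.04 and an adjusted p of 0.747, as did limma without a trend (0.0836), edgeR (0.0537 with TMM), DESeq2 (0.0529) and sample weights (0.0587). Angiogenic sprouting genes, 14 of 20 lower at a median of -0.13 and an adjusted p of 0.0413 (adjusted p = 0.701 with an estimated correlation), lost the call after GC correction, at -0.01 and an adjusted p of 0.625. They also lost it with quantile normalisation, at an adjusted p of 0.54, with limma without a trend (0.111) or with a robust prior (0.0574), with edgeR (0.109 with TMM), with DESeq2 (0.128) and with sample weights (0.0941), and without control replicate 3, at -0.11 and an adjusted p of 0.156, and without Tbx1cko replicate 2, at -0.02 and 0.561. The median was -0.23 without Tbx1cko replicate 1.

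Immediate early and dissociation stress genes had the smallest camera p of the 37 lists. The labels give no batch, so a difference in the handling of the cells cannot be told apart from genotype here and was not tested. Of the 26 members 25 were lower in Tbx1cko, with a median of -0.70 and an adjusted p of 1.965e-13 (adjusted p = 0.557 with an estimated correlation). The median was -0.43 without control replicate 2. The heat shock gene Hspa1b had 18028.7, 18867.3 and 6046.5 normalised reads in control replicates 1 to 3 and 3450.8 and 3488.3 in Tbx1cko. Hspa1b and Hspa1a are near-identical copies, so each count is uncertain. Egr3 had 852 ± 366 in controls (SD, n = 3) and 333 ± 84.8 in Tbx1cko (SD, n = 2), and Fosl1 had 625 ± 169 and 345 ± 24.3. GC correction moved the log2 difference of Fosl1 from -0.83 to -0.48 and that of Egr3 from -1.29 to -1.21. Adjusted over the list alone, 0 members passed with all libraries (limma, 5 at an unadjusted p under 0.05), and 15 passed without control replicate 2, all lower.

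Cell division genes were higher in Tbx1cko. In the mitotic cell cycle list 26 of 26 members were higher, with a median log2 difference of 0.78 and a camera adjusted p of 2.179e-06 (adjusted p = 0.706 with an estimated correlation). The kinase gene Cdk1 had 397 ± 175 normalised reads in controls and 628 ± 96.6 in Tbx1cko, and Nusap1 had 189 ± 146 and 393 ± 9.55. The groups did not overlap for 4 of the 26, where chance gives 10% per direction. This is about the share over all genes tested, where 2030 of 14339 were higher without overlap. In the DNA replication list 25 of 27 members were higher, with a median of 0.36 and an adjusted p of 0.000515 (adjusted p = 0.706 with an estimated correlation). The ribonucleotide reductase gene Rrm2 had 430 ± 213 and 743 ± 53.0. Control replicate 2 held the lowest values of Cdk1, Nusap1 and Rrm2, and without it the log2 difference of Cdk1 moved from 0.75 to 0.39, that of Rrm2 from 0.92 to 0.49, and that of Nusap1 to 0.63. Without it the medians were 0.31 for the mitotic and 0.19 for the replication list, and no member of either passed adjusted over the list alone. Without Tbx1cko replicate 1 the replication median was 0.15, at an adjusted p of 0.285, and without Tbx1cko replicate 2 it was 0.54.

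Myeloid markers were higher in Tbx1cko. Whether the share of leukocytes among the sorted cells differed between the groups was not tested. For the lower endothelial lists, a different share cannot be told apart from a change within endothelial cells. The macrophage and monocyte list had 21 of 23 members higher, with a median of 0.42 and a camera adjusted p of 0.000183 (adjusted p = 0.686 with an estimated correlation). Lyz2, lysozyme, had 38328 ± 8986 normalised reads in controls (SD, n = 3) and 50385 ± 4303 in Tbx1cko (SD, n = 2), and Chil3 had 257 ± 206 and 734 ± 140. The median was 0.20 without control replicate 2, where 1 member passed adjusted over the list alone. With sample weights, added after the data were seen, it was 0.11 and the call was lost, at an adjusted p of 0.474. The neutrophil list had 11 of 13 members higher, with a median of 0.59 and an adjusted p of 0.00564 (adjusted p = 0.557 with an estimated correlation). S100a9 had 134.5, 14.7 and 56.5 normalised reads in control replicates 1 to 3 and 301.8 and 190.6 in Tbx1cko. Without control replicate 2 the log2 difference of Chil3 moved from 2.11 to 1.02 and that of S100a9 from 2.28 to 1.45. Without that library the neutrophil median was 0.63 and 6 members passed adjusted over the list alone, all higher. Without Tbx1cko replicate 1 it was 0.51, at an adjusted p of 0.0941, without control replicate 3 it was 0.94, and without Tbx1cko replicate 2 it was 1.33.

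Genes of fatty acid uptake and oxidation were higher, 15 of 21, with a median of 0.28 and a camera adjusted p of 0.00319 (adjusted p = 0.557 with an estimated correlation). Fabp4, a fatty acid binding protein of capillary endothelium, had 49630 ± 1446 normalised reads in controls (SD, n = 3) and 70243 ± 9220 in Tbx1cko (SD, n = 2), a log2 difference of 0.50 (SE 0.16). Fabp5 had 5226 ± 869 and 8237 ± 1501, a log2 difference of 0.66 (SE 0.231), and the lipoprotein lipase gene Lpl 4769 ± 1356 and 9744 ± 4256. After GC correction the log2 difference of Fabp4 turned to -0.09, that of Lpl went down to 0.49 and that of Fabp5 was 0.59, while the list stayed called at a median of 0.11 and an adjusted p of 0.00244. The call was lost without control replicate 1, at a median of 0.16 and an adjusted p of 0.0839, without control replicate 3, at 0.25 and 0.075, and without Tbx1cko replicate 2, at 0.21 and 0.0571. Cytosolic ribosomal protein genes were lower in 40 of 52 cases, with a median of -0.19 and an adjusted p of 0.0175 (adjusted p = 0.741 with an estimated correlation), but the median was 0.003 without control replicate 2, at an adjusted p of 0.781. The ribosomal call was also lost with quantile normalisation, at an adjusted p of 0.747, after GC correction, at 0.553, without control replicate 1, at an adjusted p of 0.0816, and without Tbx1cko replicate 2, at 0.0865, and the median was -0.37 without control replicate 3.

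**Figure D3:**
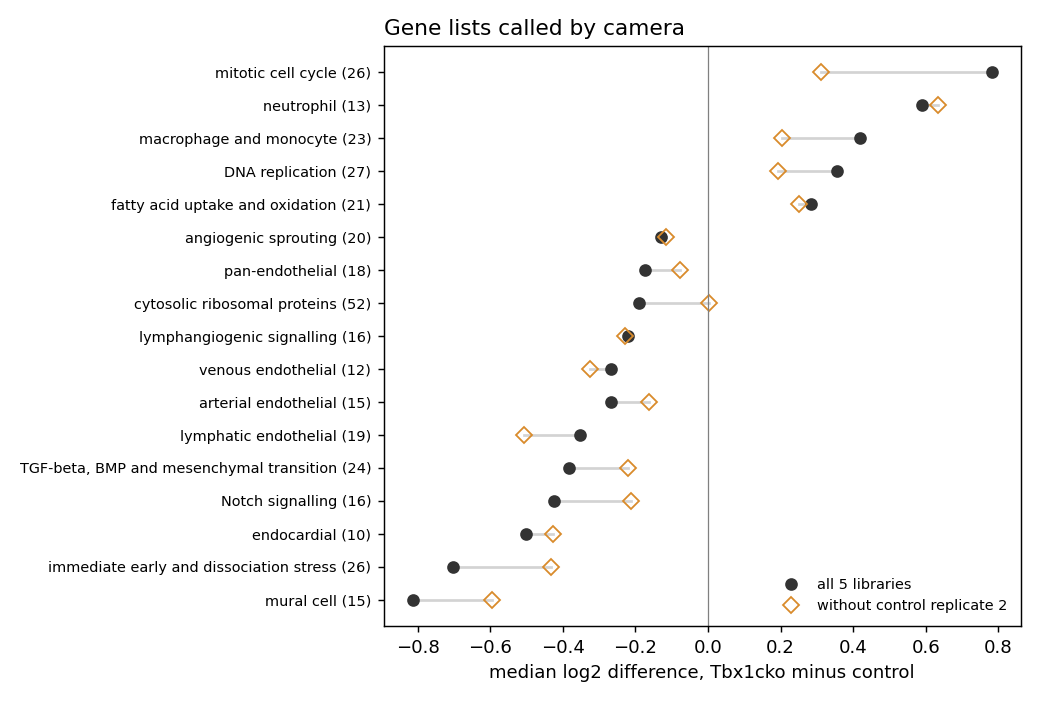
Median log2 difference (Tbx1cko minus control, horizontal axis) of the members of the 17 lists called by camera, with the number of tested members in parentheses, over all 5 libraries (filled circles) and without control replicate 2 (open diamonds). Mural cell genes are lowest, at -0.81 and -0.60, and mitotic genes highest over all 5 libraries, at 0.78.

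The other 20 lists were not called with all 5 libraries. Among markers of other cells, fibroblast genes had a median of -0.03 (adjusted p = 0.627), cardiomyocyte genes -0.03 (adjusted p = 0.987), T and NK cell genes 0.17 (adjusted p = 0.56), B cell genes -0.001 (adjusted p = 0.93), dendritic cell genes 0.22 (adjusted p = 0.478), platelet and megakaryocyte genes 0.20 (adjusted p = 0.332) and erythroid genes -0.28 (adjusted p = 0.478). Capillary endothelial genes had a median of -0.12 (adjusted p = 0.912), with 6 of 15 higher. Interferon response genes had a median of 0.18 (adjusted p = 0.216), MHC class I genes -0.25 (adjusted p = 0.0912), MHC class II genes -0.15 (adjusted p = 0.32), leukocyte adhesion genes 0.01 (adjusted p = 0.478) and chemokines 0.14 (adjusted p = 0.403). Inflammatory cytokines and NF-kappaB targets had 0.04 (adjusted p = 0.93), immune suppression genes 0.25 (adjusted p = 0.47), matrix genes 0.03 (adjusted p = 0.478), hypoxia and glycolysis genes -0.08 (adjusted p = 0.962) and oxidative phosphorylation genes -0.05 (adjusted p = 0.93). The 20 tested genes that neighbour Tbx1 in the region syntenic to human 22q11 had a median of -0.05 (adjusted p = 0.258), and 0 of them passed by limma, with 1 at an unadjusted p under 0.05 and none called by DESeq2 without control replicate 2. For 10 of these lists median, mean and test did not all have the same sign: MHC class II, matrix, leukocyte adhesion, inflammatory, fibroblast, capillary, B cell, oxidative phosphorylation, hypoxia and cardiomyocyte genes.

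Several of these 20 lists were called once a single library was left out, some with a changed direction. Cardiomyocyte genes were higher without control replicate 2, at a median of 0.32 and an adjusted p of 6.51e-07, as were oxidative phosphorylation genes (0.05, adjusted p = 0.0149), capillary endothelial genes (0.08, adjusted p = 0.0473) and platelet genes (0.24, adjusted p = 0.0473). Inflammatory genes were lower without that library, at -0.16 (adjusted p = 0.0149), and so were fibroblast genes, at -0.16 (adjusted p = 0.00514), which with the sex-linked list makes 7 lists newly called. Fibroblast genes were higher without Tbx1cko replicate 1, at 0.43 (adjusted p = 0.00728), and lower without Tbx1cko replicate 2, at -0.41 (adjusted p = 7.47e-05). Erythroid genes went from -1.20 (adjusted p = 5.33e-07) without Tbx1cko replicate 1 to 0.53 (adjusted p = 0.000624) without Tbx1cko replicate 2. Platelet genes were at 0.55 (adjusted p = 0.00821) without Tbx1cko replicate 2. Without Tbx1cko replicate 1, T and NK cell genes were at 0.42 (adjusted p = 0.0485) and the neighbours of Tbx1 at -0.18 (adjusted p = 0.0125). MHC class I genes were at -0.49 (adjusted p = 0.0167) without control replicate 3. Hypoxia and glycolysis genes were called higher after GC correction, at 0.05 (adjusted p = 0.0358). The estimation of the sample weights stopped before it converged, which limits the calls made with them. With sample weights, 5 of the 20 lists were called: MHC class II genes at -0.20 (adjusted p = 0.0239), inflammatory genes at -0.21 (adjusted p = 0.0239) and fibroblast genes at -0.37 (adjusted p = 0.000417), all lower, and cardiomyocyte genes at 0.22 (adjusted p = 0.0264) and platelet genes at 0.42 (adjusted p = 0.0424), both higher. DESeq2 without control replicate 2 also called leukocyte adhesion genes, at -0.02 (adjusted p = 0.0331), and matrix genes, at -0.07 (adjusted p = 0.0184), both lower.

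The sex-linked list was not called (adjusted p = 0.239), but its genes differed between libraries of a group. Xist, which is transcribed from the inactive X chromosome of females, had 12967.7 normalised reads in Tbx1cko replicate 2 and 16.9, 0, 1.9 and 0 in control replicates 1 to 3 and Tbx1cko replicate 1. The Y-linked genes Kdm5d, Ddx3y, Eif2s3y and Uty had 0, 3.1, 0 and 2 in Tbx1cko replicate 2. In control replicate 2 they had 205.1, 43.2, 50.6 and 36.8, far below control replicate 1 (485.9, 1673.4, 639.5 and 502.8), control replicate 3 (476.1, 2116.2, 677.5 and 528.8) and Tbx1cko replicate 1 (472.9, 1928.9, 693.3 and 424.4). Their transcripts are poor in GC, at 43.8, 36.1, 36.4 and 35.8%. In the tenth of genes poorest in GC, control replicate 2 had a median log2 deviation of -2.33. Whether this accounts for its low Y-linked counts was not tested. The sex-linked list was called lower without Tbx1cko replicate 1, at a median of -7.05 and an adjusted p of 2.28e-05, and without control replicate 2, at -4.41 and 0.00842. Leaving out either Tbx1cko replicate leaves a single library in that group, so such a fit cannot show what the difference in sex contributed.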

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

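The GC correction, sample weights, the lymphatic list without Tbx1, and edgeR, DESeq2 and GC correction without control replicate 2 were chosen after the data were seen. The count of 0 genes past the threshold held in limma under both other pseudocounts, both other filters, TMM scaling, quantile normalisation, no trend, a robust prior and both other thresholds, and in voom and both edgeR fits. Leaving out a library gave 0 to 3 genes (0 to 1 higher, 0 to 2 lower), the 3 without control replicate 2. DESeq2 called 4 genes (1 higher, 3 lower), and simulated counts with the spread of all 5 libraries also gave DESeq2 false calls. Without control replicate 2, edgeR called 1 gene (0 higher, 1 lower), DESeq2 65 (26 higher, 39 lower) and limma with GC correction 0. Sample weights gave 760 (288 higher, 472 lower). Their weights ran from 0.0606 for control replicate 2 to 19.1 for control replicate 1, and their estimation stopped before it converged. The cause of these differences was not tested beyond the libraries left out.

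Tbx1 was lower under each alternative, from -1.42 after GC correction to -2.03 after quantile normalisation. It passed with DESeq2 at -1.955, with sample weights at -1.802 and with DESeq2 without control replicate 2 at -1.924. The filter at 50 removed Tbx1, Myt1l, Siglecf and Fam65c, which have no value there. Of the results of the 11 other named genes under the alternatives, 228 stayed short of the threshold and 22 passed it, all in the same direction. Where a Tbx1cko replicate was left out, the lone library was assumed to vary like the controls. Its adjusted p ranged from 0.0127 to 0.996, and the cause was not tested.

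The number of lists called by camera, 17, was 14 to 24 under the other settings, and 0 with an estimated correlation or by fry for a single direction. Over the alternatives that kept the preset correlation, 347 results of these 17 lists kept their call and 44 lost it. The losses of all 17 calls with an estimated correlation and by fry for a single direction are not in these counts. Only the ribosomal protein list reversed, at 0.030 with GC correction and without control replicate 2. The cause was not tested.

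With the replicate block 3 genes were called (1 higher, 2 lower), and the genes at an unadjusted p under 0.05 turned to mostly higher (1392 higher, 214 lower). The MHC class I, erythroid and sex-linked lists became called, all lower, and the lymphatic, venous, angiogenic sprouting and fatty acid lists lost their calls. The numbers are not known to pair the samples: deviations of same-numbered libraries correlated at -0.056 and -0.046.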

Other observations

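The tests of GC content, read totals, macrophage genes, sex and cell loss were chosen after the results they bear on were seen, as were the GC correction, the lymphatic list without Tbx1 and the fits without control replicate 2 other than limma's. Among the 65 genes that DESeq2 called without control replicate 2 were genes in none of the lists, all chosen after their values were seen. The aggrecanase gene Adamts4 had 6737 ± 705 normalised reads in controls (SD, n = 3) and 4283 ± 314 in Tbx1cko (SD, n = 2), with a DESeq2 log2 difference of -0.75 (adjusted p = 9.45e-05), and Steap4, a metalloreductase gene, had 1389 ± 209 and 760.5 ± 14.8 (adjusted p = 0.000202). The innate immune receptor gene Tlr13 had 505.1, 47.8 and 669.9 in control replicates 1 to 3 and 955.8 and 1139.3 in Tbx1cko (adjusted p = 0.00781). The survival gene Bcl2l1 had a DESeq2 log2 difference of 0.81 (adjusted p = 0.00289), but its value in control replicate 2, 2858.8, lay between the Tbx1cko values of 2428.3 and 3097. GC correction over all 5 libraries moved the limma log2 difference of Adamts4 from -0.65 to -0.41. With all 5 libraries none of these genes passed in limma.

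Inflammatory genes went both ways. Tnf had 863 ± 170 normalised reads in controls and 1412 ± 246 in Tbx1cko, and Il23a 6.52 ± 2.37 and 30.7 ± 3.11, while the adhesion receptor gene Icam1 had 12560 ± 2223 and 7999 ± 1311. The chemokine gene Ccl6 had 1885 ± 600 and 3602 ± 564. Osteopontin (Spp1) had 7126 ± 3624 and 15497 ± 1016, and the collagen VI gene Col6a2 1715 ± 388 and 967 ± 161. GC correction moved the log2 difference of Spp1 from 1.23 to 0.70, that of Icam1 from -0.65 to -0.40 and that of Ccl6 from 0.97 to 0.62. Each of Tnf, Il23a, Icam1, Ccl6, Spp1 and Col6a2 had a limma unadjusted p under 0.05 and an adjusted p of 0.762. Cyp26b1, which encodes a retinoic acid hydroxylase, had 293.8, 5369.9 and 318 in control replicates 1 to 3 and 83.2 and 45.9 in Tbx1cko. The atrial muscle genes Myl7 and Sln were also highest in control replicate 2, at 320.1 and 91.1, against 72.3 and 53.6 for Myl7 and 31.6 and 8.5 for Sln in the other controls. In Tbx1cko replicates 1 and 2 they were at 10.1 and 9.2 for Myl7 and 4.6 and 0 for Sln.

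Control replicate 2 lay apart from the other 4 libraries and set the spread of the control group, with a first principal component that held 84.7% of the variance. Fewer reads are argued against, because this library had the most, 18617284. A lack of macrophages alone is argued against too: macrophage list genes above the list's median GC content deviated by -0.28 on average (11 genes) and the others by -2.25 (12 genes), a difference of 1.97 (2-sided exact permutation p = 0.000134). The genes come from a single library and are not independent, so this p measures no spread between libraries. Because this library's deviations followed GC content over all genes, such a split was likely for any list. Fewer macrophages on top of that trend were not tested and stay open. A trend with GC content was present in this library, with a Spearman rho of 0.801 across genes. Whether a technical bias caused it stays open. Removing the trend raised the library's correlations with the others to between 0.928 and 0.94. The highest correlation of each other library was then 0.986 to 0.988, so a difference remained in control replicate 2. Its high Cyp26b1, Myl7 and Sln counts were not tested, nor was any other biological explanation.

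The mural cell genes may have been lower because fewer pericytes and smooth muscle cells, which a CD31 sort should remove, came through it from the Tbx1cko hearts. A GC bias of control replicate 2 as the whole cause is argued against, since the median without that library was -0.595, beyond the members' median absolute deviation of 0.152, and -0.61 with GC correction as well. Fewer mural cells should lower all members alike, but only where no other sorted cells express those genes. The spread of the members thus cannot tell fewer cells from a change within the cells. Without control replicate 2 the middle 50% of members spanned 0.358, under a bound of 0.622 set at 4 standard errors, for any member left out (0.278 to 0.395). All members spanned 1.23, from -1.14 for Vtn to 0.095 for Des. The different sex of Tbx1cko replicate 2 cannot be told apart either: Tbx1cko replicate 1 alone had a median of -0.512 against control replicates 1 and 3, which is a single library. Rgs5, the most abundant member of the list, had 24935 ± 14194 normalised reads in controls and 25233 ± 2659 in Tbx1cko, a log2 difference of 0.25 that was -0.39 without control replicate 2 and -0.50 after GC correction.

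For the lymphatic genes the same explanations were weighed. A GC bias of control replicate 2 as the whole cause is argued against, with a median of -0.507 without that library, beyond the members' median absolute deviation of 0.367, -0.61 with GC correction as well, and -0.48 without Tbx1 in the list. Fewer lymphatic endothelial cells cannot be told apart from a change within these cells, because other sorted cells may express members, as macrophages do Lyve1. Without control replicate 2 the middle 50% of members other than Tbx1 spanned 0.682, above the bound of 0.64. The span ran from 0.638 to 0.699 as each member was left out, a step added after the first outcome was seen. All of these members spanned 0.958. Sex cannot be told apart either, with a median of -0.416 in Tbx1cko replicate 1 alone. Loss of Tbx1 in endothelial cells, which the design names, stays among the open explanations.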
